A study of Mus musculus with 20 samples.

How the data were processed

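The series covered CD4+/CD8+ double-positive thymocytes of C57BL/6 mice, an intermediate stage of T-cell development in the thymus, profiled by chromatin immunoprecipitation and sequencing (ChIP-seq) and by FAIRE, which isolates open chromatin without an antibody. Of its 20 samples, 16 had a peak list, with 1 list per target. These targets were total RNA polymerase II (Pol II), Pol II phosphorylated on serine 5 (Ser5P) or serine 2 (Ser2P) of its C-terminal repeats, TBP, Taf1, TFIIA, TFIIB, TFIIE, TFIIF, TFIIH, CBP, ETS1, H3K4me1, H3K4me3, H3K36me3 and FAIRE. The other 4 samples, total RNA, poly(A) RNA, input and rabbit immunoglobulin control, were not analysed here.

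Each deposited list gave the chromosome, start, end and area of its peaks, and the area was, by the names of the deposited files, the area under the authors' signal track over the peak. Per the track names in the deposited files, every track but that of FAIRE had artefact regions removed, was scaled and was background-subtracted, and the FAIRE track name recorded none of these steps. Peak ends fell on bins of 10 bp. Per the submitters' processing notes the genome build was mm9, and all coordinates are given in that build. Per the labels' protocols, sheep anti-rabbit beads were used for ETS1 and Protein-G beads for the other immunoprecipitations. Per the names of the deposited files and tracks, replicates had been merged before 13 of the lists were made, and the CBP, Taf1 and TFIIB lists came from 1 replicate each. The aligner, the peak caller and the peak threshold are not given in the sources used here, and neither are read numbers, so the depth behind each list was unknown. The areas are the authors' values and were used only to rank, filter or match peaks within a list.

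Overlap meant at least 1 bp in common. A platform was the union of total Pol II and TBP peaks that overlapped each other. Platforms, CBP peaks and ETS1 peaks were called H3K4me3-marked if they overlapped an H3K4me3 peak, H3K4me1-only if they overlapped an H3K4me1 peak and no H3K4me3 peak, and unmarked otherwise. Shares carry Wilson 95% intervals, which cover counting error only. Differences carry 95% intervals from a bootstrap over whole chromosomes with 1000 draws and 21 chromosomes. Such an interval measures variation along the genome in these lists, not between animals. A difference was called when its interval excluded 0. With 1 list per target there was no spread between replicates and no p-value was computed. Random placement shifted the peaks of a list along each chromosome as a circle, 100 times.

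Regions were named by a rule fixed before the data were examined. It took the 5 widest H3K4me3-marked and the 5 widest H3K4me1-only platforms, the 3 peaks of highest area of CBP, ETS1, TFIIF and Ser2P, and the 5 H3K4me1-only platforms with the most of the 6 general factors Taf1, TFIIA, TFIIB, TFIIE, TFIIF and TFIIH. Genome sequence and gene annotation of mm9 were not used here. The planned work on start sites, gene lists, markers of other cell types and CpG content was therefore not run, and regions are given by position without a gene.

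Alternatives covered the overlap rule, the authors' threshold, list length, the sex chromosomes, the way platforms were built, the definition of the classes, matching on platform width, and covered length in place of peak number. Others were added after seeing the data and are named where they appear. The pairs of lists given in the text were picked after the overlaps of all pairs had been computed. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used. The overlap code was tested on simulated data, where shares of 5000 simulated peaks in H3K4me3 peaks were recovered with an error of 0 percentage points. Those peaks were centred on H3K4me3 peaks or placed well away from them by the same overlap rule. That result was therefore built in and checks the counting only. The 15651 TBP peaks placed at random gave an overlap with H3K4me3 of 0.973 times that of random placement, and 95 of 100 bootstrap intervals held the true difference of shares. The simulated shares were the same on every chromosome, so coverage where shares vary between chromosomes was not tested.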

Results

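Double-positive thymocytes were mapped for RNA polymerase II, for the general transcription factors that assemble with it at start sites, for the coactivator CBP, for the T-cell transcription factor ETS1, for 3 histone modifications and for open chromatin. The series title names initiation platforms and the recruitment of general factors at enhancers and promoters. The lists were therefore compared between chromatin with H3K4me3, the usual mark of active promoters, and chromatin with H3K4me1 but no H3K4me3, as found at many enhancers. The 16 lists held 270514 peaks. Total Pol II had 18037 peaks, TBP 15651, Taf1 13518, TFIIE 11678, FAIRE 11176, TFIIB 10999, Ser5P 10644, TFIIH 8618, TFIIA 6588, CBP 6372, ETS1 2359, Ser2P 1811 and TFIIF 1262. Factor peaks were narrow, with median widths from 80 bp for CBP to 320 bp for Ser2P. The histone lists were broader, with 28013 H3K4me3 peaks over 23.0 Mb, 74607 H3K4me1 peaks over 69.4 Mb and 49181 H3K36me3 peaks over 104 Mb. Without replicate lists, no difference could be set against a spread between animals.

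The lists differed in the chromatin of their peaks. Most peaks of Ser5P, the form of Pol II near initiation, lay in H3K4me3 peaks, at 78.7% (95% Wilson interval 77.9 to 79.4). TFIIB, which bridges TBP and Pol II, followed at 69.7% (68.8 to 70.5), then TBP at 66.3% (65.6 to 67.0), total Pol II at 64.3% (63.6 to 65.0), ETS1 at 61.4% (59.4 to 63.3) and TFIIE at 60.4% (59.5 to 61.3). FAIRE stood at 45.9% (45.0 to 46.8). TFIIF, CBP and TFIIH were lower, at 35.8%, 29.3% and 22.2%, and TFIIA and Ser2P had 17.8% and 14.7%. Taf1, the largest TFIID subunit, had 8.57% (8.11 to 9.06).

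These shares were above random placement for all 13 lists, from 8.30-fold for Taf1 to 68.5-fold for Ser5P. Outside both H3K4 marks lay 87.9% of Taf1 peaks, 75.9% of TFIIA peaks, 70.5% of TFIIH peaks and 53.8% of CBP peaks, against 16.5% of TFIIB and 5.64% of ETS1 peaks. Few peaks of Taf1 (1.78%), TFIIH (6.23%) and TFIIA (7.26%) overlapped FAIRE, against 28.9% of TFIIB, 24.7% of TBP and 23.7% of TFIIE peaks. Even the Taf1 share was 17.8-fold above random placement. ETS1 had the highest share of H3K4me1-only peaks, 33.0% (31.1 to 34.9). With every factor list reduced to its 1262 peaks of highest area, the share in H3K4me3 peaks was 92.9% for TFIIE, 54.6% for CBP and 9.90% for Taf1.

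**Figure D1:**
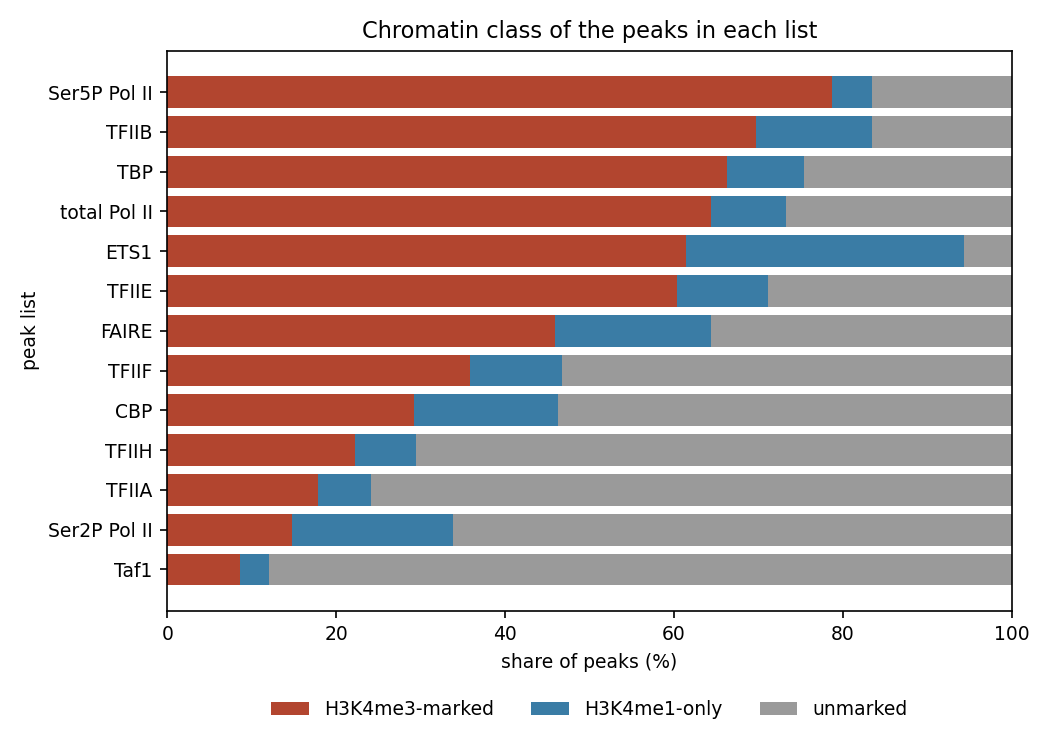
Horizontal bars give, for each of 13 peak lists, the percentage of peaks that overlapped H3K4me3 (red), H3K4me1 without H3K4me3 (blue) or neither (grey). Ser5P leads with 78.7% in H3K4me3 peaks, and Taf1 has 87.9% outside both marks.

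Total Pol II and TBP, the factor that nucleates preinitiation complexes, formed 8649 joint platforms. Of these, 6567 (75.9%, 75.0 to 76.8) were H3K4me3-marked, 469 (5.42%, 4.96 to 5.92) were H3K4me1-only and 1613 (18.6%, 17.8 to 19.5) were unmarked. H3K4me3-marked platforms were the widest, with a median of 280 bp and quartiles of 210 and 390 bp. H3K4me1-only platforms had a median of 200 bp (140 and 270), and unmarked platforms one of 130 bp (120 and 140). The ratio of medians of H3K4me3-marked to H3K4me1-only platforms was 1.4 (bootstrap interval 1.33 to 1.56). Platforms of 1000 bp or wider numbered 129, and 128 of them were H3K4me3-marked. With lists reduced to equal length, only 10 H3K4me1-only platforms were left and the ratio was 1.02 (0.811 to 1.21). With total Pol II peaks alone as platforms the classes held 11606, 1605 and 4826.

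Among the widest H3K4me3-marked platforms, 3 of 5 lay side by side on chromosome 11, at 52080671 to 52084640, 52086181 to 52092050 and 52092191 to 52096170. The middle one spanned 5870 bp and carried peaks from 14 of the 16 lists. Ser2P, the form of elongating Pol II, had 2 of its 3 peaks of highest area next to them, at 52063941 to 52070630 and 52070701 to 52076520. The whole stretch of 32.2 kb held 43 Ser5P peaks, 24 TBP peaks and no ETS1 peak. This stretch was singled out after its values were seen. The remaining wide platforms were on chromosome 1 at 135971361 to 135975820 (4460 bp) and on chromosome 6 at 41491341 to 41495130 (3790 bp). The ETS1 peak of highest area lay on chromosome 6 as well, at 41504341 to 41504730, with peaks of CBP, FAIRE, TBP and total Pol II.

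H3K4me1-only platforms were shorter even at their widest. The first, on chromosome 11 at 101519161 to 101520390, spanned 1230 bp and overlapped peaks of CBP, FAIRE, Ser5P, TFIIB, TFIIE and TFIIH. It was followed by platforms of 950 bp on chromosome 13 at 73840101 to 73841050, 860 bp on chromosome 15 at 82979721 to 82980580, 700 bp on chromosome 16 at 10668501 to 10669200 and 690 bp on chromosome 10 at 39978191 to 39978880. All 5 had Ser5P, TFIIB and TFIIE peaks, and none had a Taf1 peak. Peaks of all 6 general factors lay at 4 H3K4me1-only platforms. These measured 330 bp on chromosome 1 at 99476881 to 99477210, 140 bp on chromosome 12 at 26123151 to 26123290, 140 bp on chromosome 13 at 109651371 to 109651510 and 130 bp on chromosome 3 at 157276601 to 157276730. The next, with 5 of the 6, spanned 550 bp on chromosome 13 at 23790161 to 23790710. Only the first and the last of these overlapped a FAIRE peak.

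**Figure D2:**
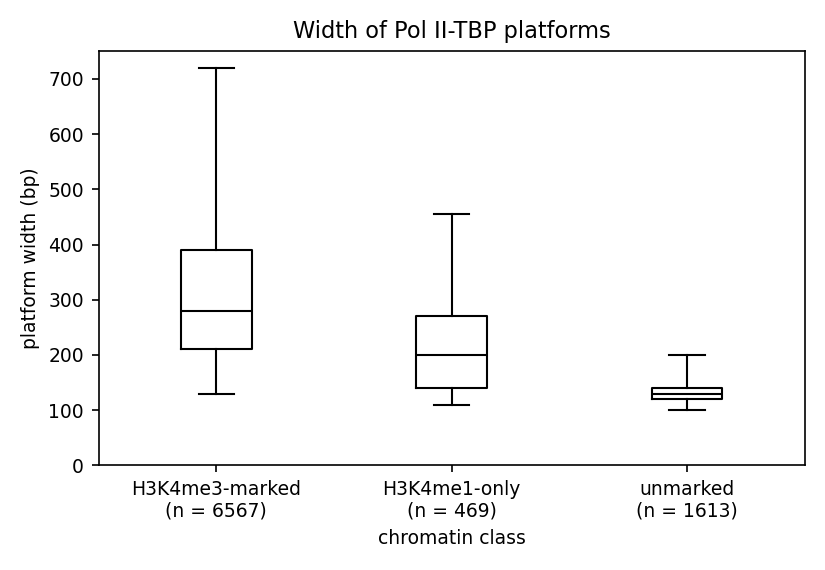
Boxes show the median and quartiles of platform width in bp for each chromatin class, and whiskers reach the 5th and 95th percentiles. Medians fall from 280 bp to 200 bp and 130 bp.

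Of the 11 lists, Ser5P and CBP differed most in occupancy between H3K4me3-marked and H3K4me1-only platforms. Ser5P peaks lay at 69.1% (68.0 to 70.2) of H3K4me3-marked and 35.2% (31.0 to 39.6) of H3K4me1-only platforms, a difference of 33.9 percentage points (bootstrap interval 29.7 to 37.9). CBP, a histone acetyltransferase often used to mark enhancers, went the other way, with 14.2% against 27.5%, a difference of -13.3 points (-18.3 to -9.19). Unmarked platforms had CBP peaks at 22.2%, so the excess was not limited to H3K4me1-only ones. TFIIE, which recruits TFIIH, was at 61.9% and 62.0% (difference -0.177, -5.16 to 4.50). With the classes matched on width, the Ser5P difference was 18.6 points (14.4 to 22.6; 17.0 when matched on Pol II and TBP area, added after seeing the data), the CBP difference -16.8 (-21.5 to -12.8) and the TFIIE difference -15.4 (-21.0 to -9.82). With total Pol II peaks alone as platforms, CBP differed by -2.03 points (-5.15 to 0.292) and TFIIE by 18.1 points (13.7 to 21.6). With lists of equal length, which left 10 H3K4me1-only platforms, the Ser5P difference was 5.19 points (-15.9 to 29.7).

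TFIIB peaks were found at 64.1% of H3K4me3-marked and 52.7% of H3K4me1-only platforms, 11.4 points apart (8.49 to 15.0), but this difference was -3.06 (-6.28 to 0.689) after matching on width and -4.52 (-7.88 to -1.58) in the upper 50% of each list by area. TFIIH (18.9% against 27.3%, -8.35 points, -11.4 to -6.01) and TFIIF (3.78% against 9.38%, -5.61 points, -8.41 to -2.90) were more frequent at H3K4me1-only platforms. At platforms with a FAIRE peak, a restriction added after seeing the data, the TFIIH difference turned to 6.10 points (1.32 to 10.5) and the TFIIF difference was -0.0272 (-3.09 to 3.06). In the upper 50% of each list by area they were 1.02 (-1.73 to 3.51) and -1.22 points (-2.34 to -0.0888). After matching on width they were larger, at -15.0 (-18.0 to -12.5) and -6.48 points (-9.41 to -3.71). With total Pol II alone, TFIIH differed by 0.441 points (-2.63 to 2.67) and TFIIF by -1.12 (-2.02 to -0.387). Taf1 differed by -3.14 points (-7 to -0.199), which was -3.13 (-6.55 to 0.0477) on autosomes, 3.83 (2.20 to 5.33) in the upper 50% of each list by area and 10.4 (6.77 to 13.3) at platforms with a FAIRE peak. Matching enlarged the Taf1 difference, to -6.50 (-10.3 to -3.54) on width and -7.54 (-11.4 to -4.59) on Pol II and TBP area. The upper 50% setting also dropped the weaker H3K4me3 and H3K4me1 peaks, so platforms changed class. Cutting the H3K4me3 list alone moved the TFIIB, TFIIH and Taf1 differences in the same direction. Effects of peak strength and of changed class therefore cannot be told apart in that setting. ETS1, TFIIA, Ser2P and FAIRE did not pass the test between these classes. Their differences were -3.14, -2.45, -1.14 and 2.60 points. These 4 values depended on the setting. TFIIA was at -7.10 points (-10.1 to -4.17) after matching on width and at 8.06 (4.79 to 11.1) at platforms with a FAIRE peak, and FAIRE at -5.18 (-8.83 to -1.96) after matching on width. With total Pol II alone, Ser2P differed by -16.2 points (-20.4 to -11.8), FAIRE by 12.3 (9.02 to 14.9) and ETS1 by 1.77 (0.110 to 3.20), against -5.46 (-8.79 to -2.01) for ETS1 after matching on width. Taf1 and ETS1 peaks happened to lie at equal numbers of platforms, 732 H3K4me3-marked and 67 H3K4me1-only ones, although just 74 and 4 of these held both.

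Unmarked platforms had a different make-up. Taf1 peaks lay at 65.0% (62.7 to 67.3) of them, TFIIH peaks at 67.4%, TFIIE peaks at 60.6%, TFIIA peaks at 43.8% and TFIIF peaks at 17.1%. CBP peaks lay at 22.2% (20.2 to 24.3), a difference of -7.99 points (-10.6 to -5.50) for H3K4me3-marked minus unmarked platforms. In contrast, TFIIB was at 5.58% (4.56 to 6.81), FAIRE at 4.40% (3.50 to 5.52) and ETS1 at 0.186% (3 of 1613 platforms). Of the 11 lists, all but TFIIE differed between H3K4me3-marked and unmarked platforms by the bootstrap interval. In the upper 50% of each list by area, with 566 unmarked platforms, the difference fell from 45.3 to 9.86 points (4.38 to 15.0) for Ser5P, from 58.5 to 28.6 for TFIIB and from 35.7 to 9.87 for FAIRE, and moved from -53.9 to -17.9 for Taf1 and from -48.4 to -16.2 for TFIIH. That setting also dropped the weaker H3K4me3 and H3K4me1 peaks, so platforms lying only in those peaks changed class. Effects of peak strength and of changed class cannot be told apart there. Ser2P turned to 0.253 points and CBP, at -3.47 (-7.97 to 0.343), no longer passed. TFIIE passed at 11.7 points there, at 20.0 with platforms from Ser5P and TBP and at 13.1 with total Pol II alone, and at -3.51 with the H3K4me3 class widened to 1000 bp. Against H3K4me3-marked platforms of the same width, a comparison added after seeing the data, the difference was 26.1 points for TFIIB and -29.0 points for TFIIE. Among the 71 unmarked platforms with a FAIRE peak, the restriction added after seeing the data, the contrast turned for Ser5P, Taf1, TFIIF, TFIIH and CBP, with H3K4me3-marked minus unmarked values of -5.59, 3.99, 2.84, 13.6 and 6.29 points, and only the interval for TFIIH (7.80 to 19.7) excluded 0. With lists of equal length only 5 unmarked platforms were left, and the differences turned to -14.8 points for Ser5P, 3.00 for Ser2P, 7.65 for Taf1, -20.8 for TFIIB, 8.49 for TFIIF and -22.5 for FAIRE.

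**Figure D3:**
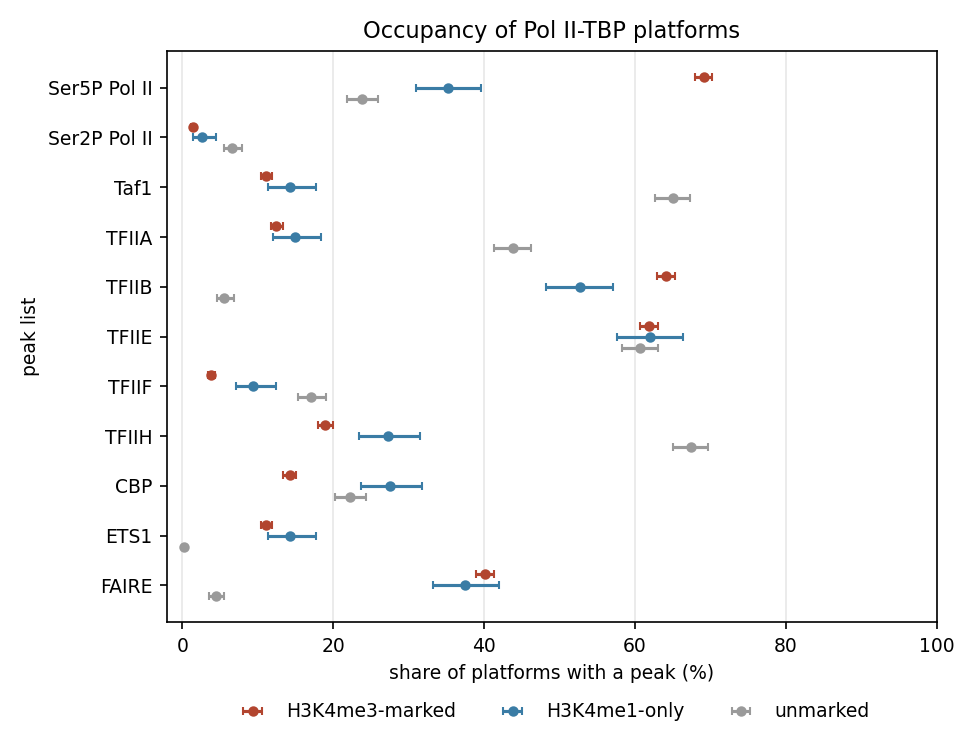
Points give the percentage of platforms in each chromatin class that overlapped a peak of each list, with Wilson 95% intervals. H3K4me3-marked platforms (red) stand apart for Ser5P at 69.1%, and unmarked platforms (grey) for Taf1 at 65.0% and TFIIH at 67.4%.

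CBP and ETS1 sites served as anchors chosen without regard to Pol II. At CBP sites, total Pol II lay at 57.9% of the 1864 H3K4me3-marked and 19.1% of the 1082 H3K4me1-only sites, a difference of 38.8 points (34.9 to 42.4). TBP lay at 56.9% and 24.7% (32.2 points, 27.6 to 36.4), TFIIB at 55.0% and 27.4% (27.6 points, 23.7 to 31.3) and Ser5P at 37.7% and 9.06% (28.6 points, 25.9 to 31.0). At ETS1 sites total Pol II lay at 56.6% of 1448 H3K4me3-marked and 13.4% of 778 H3K4me1-only sites (43.3 points, 39.9 to 46.3). TBP was at 61.3% and 26.0%, TFIIB at 61.5% and 31.0%, and TFIIE at 51.0% and 21.5%. With factor lists of equal length the total Pol II difference was 19.1 points (16.6 to 22.0) at CBP sites and 14.4 points (11.2 to 17.3) at ETS1 sites, that of TBP 14.6 and 9.59 points and that of Ser5P 15.1 and 9.74 points. The TFIIB difference was then 24.0 and 17.7 points, and TFIIE at ETS1 sites fell from 29.5 to 15.0 points.

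All 11 lists compared at each anchor were more frequent at H3K4me3-marked than at H3K4me1-only sites, with intervals above 0. The smallest differences were 1.92 points for TFIIF at CBP sites (0.179 to 3.57) and 2.15 points for Taf1 at ETS1 sites (1.05 to 3.38). TFIIF at CBP sites no longer passed in 4 alternative settings, and ETS1 at CBP sites turned to -0.758 points in the upper 50% of each list by area. With factor lists of equal length, Taf1 at CBP sites turned to -0.478 points and FAIRE at ETS1 sites to -0.0115, and Taf1 (0.290) and TFIIF (2.43) at ETS1 sites no longer passed. In the upper 50% of each list, FAIRE (1.07) and CBP (1.14) at ETS1 sites no longer passed either. That setting also cut the H3K4me3 and H3K4me1 lists, so sites changed class. With only the H3K4me3 list cut to its upper 50%, ETS1 at CBP sites was already at -0.397 points. FAIRE peaks lay at 46.1% and 31.4% of CBP sites and at 51.8% and 38.8% of ETS1 sites. The FAIRE difference at CBP sites, 14.7 points, was 5.19 in the upper 50% of each list and 6.93 with lists of equal length. It reached 21.4 with peaks within 500 bp counted as overlapping. The 3426 unmarked CBP sites had Pol II at 16.4% and TFIIB at 2.54%. They had more Taf1 (20.5% against 6.76%), TFIIH (20.3% against 15.8%) and TFIIA (11.5% against 10.6%) peaks than H3K4me3-marked CBP sites. The other lists were less frequent at them. At the 133 unmarked ETS1 sites only Taf1 was more frequent than at H3K4me3-marked ones, at 23.3% against 3.18%. No interval was computed for these differences.

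**Figure D4:**
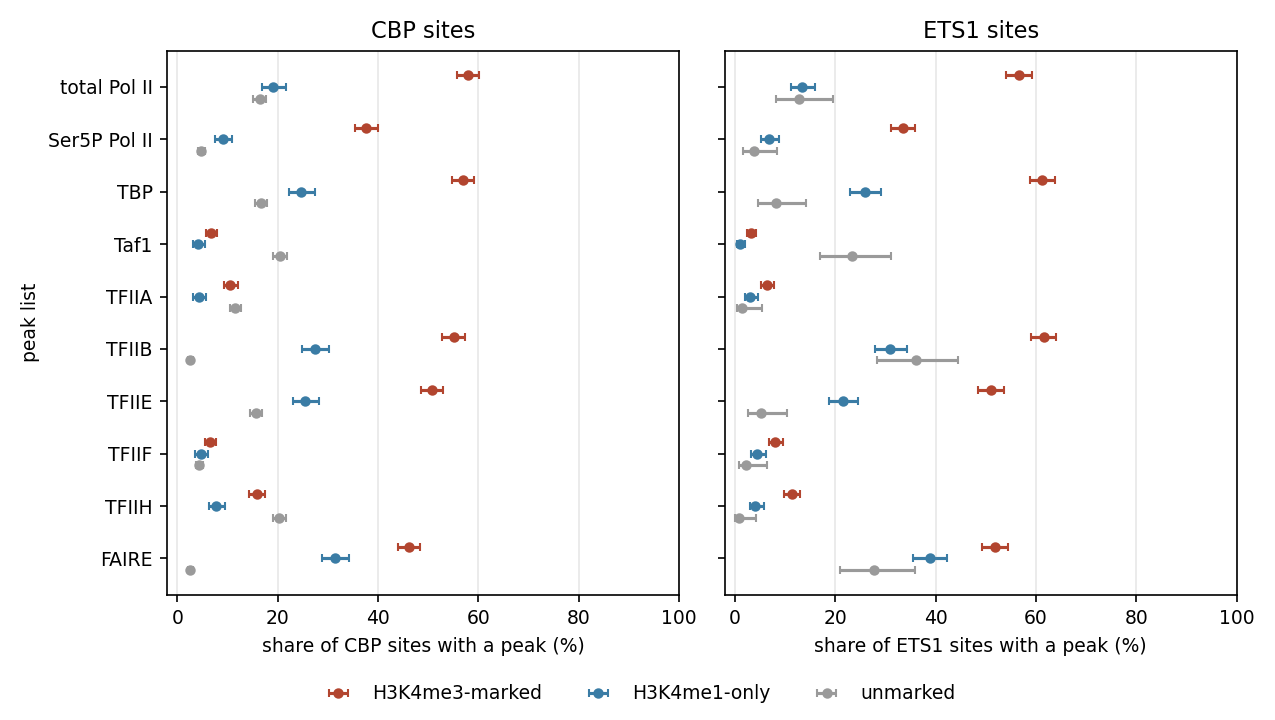
Points give the percentage of CBP sites (left) and ETS1 sites (right) of each chromatin class that overlapped a peak of each list, with Wilson 95% intervals. Total Pol II reaches 57.9% and 56.6% at H3K4me3-marked sites, against 19.1% and 13.4% at H3K4me1-only sites.

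Wider H3K4me3-marked platforms carried more of the 6 general factors. Their mean number was 2.88 in the widest quintile (430 to 5870 bp) and 0.852 in the narrowest (40 to 190 bp), a difference of 2.03 (1.95 to 2.11). Over that range TFIIB rose from 36.6% to 91.4% of platforms, TFIIE from 31.0% to 91.9%, TFIIH from 6.70% to 44.2% and Ser5P from 38.2% to 94.4%. Random placement gave means of 0.0169 and 0.00566, so overlap by chance rose with width by a similar factor, though at a far lower level. Platforms were not matched on Pol II or TBP area here, so width and signal strength cannot be told apart. In H3K4me1-only platforms the means were 2.22 and 1.98, a difference of 0.236 (-0.111 to 0.651). Random placement gave 0.0124 and 0.00468 for these platforms. There TFIIB rose with width from 17.0% to 81.7% and FAIRE from 13.8% to 58.1%, while Taf1 fell from 38.3% to 5.38% and TFIIH from 48.9% to 28.0%. Over all classes the difference was 0.550 (0.414 to 0.674), and without unmarked platforms, an alternative added after seeing the data, it was 1.86 (1.78 to 1.94), with a range of 0.363 to 1.86 over the alternatives. With factor lists of equal length the difference in H3K4me3-marked platforms was 0.710, and with total Pol II alone that in H3K4me1-only platforms was 0.667 (0.508 to 0.886).

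Ser5P and Ser2P peaks lay in different chromatin. Ser5P peaks overlapped H3K4me3 at 78.7% and H3K36me3, a mark of transcribed gene bodies, at 4.29% (3.92 to 4.70). Ser2P peaks overlapped H3K4me3 at 14.7% (13.2 to 16.5) and H3K36me3 at 53.7% (51.4 to 56.0). The differences were 63.9 points (60.6 to 67.0) and -49.4 points (-53.0 to -45.1). By covered length, 60.8% of Ser2P and 3.63% of Ser5P lay in H3K36me3 peaks. The Ser2P list was far shorter, with 1811 peaks against 10644, and 13.5% of Ser2P peaks overlapped a Ser5P peak. Its 3 peaks of highest area, 2 on chromosome 11 and 1 on chromosome 17 at 51875141 to 51879600, all overlapped Ser5P, total Pol II, H3K36me3 and H3K4me1 peaks and no TBP peak.

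TBP peaks overlapped total Pol II 251-fold more often than under random placement, and ETS1 peaks overlapped CBP 541-fold more often. Overlap with H3K36me3 lay below random placement for several lists, at 0.157-fold for ETS1, 0.365-fold for TBP and 0.376-fold for TFIIB. The share of TBP peaks in total Pol II was 60.9% (60.1 to 61.6), and total Pol II peaks overlapped TBP at 50.0% (9019 peaks). TFIIE peaks overlapped total Pol II at 61.8% and TFIIB peaks overlapped TBP at 53.0%. TFIIH peaks overlapped Taf1 at 35.9%, and TFIIA peaks overlapped Taf1 at 24.4%. ETS1 peaks overlapped CBP at 28.9% (27.1 to 30.8) and FAIRE at 46.2%, and CBP peaks overlapped ETS1 at 11.0% and FAIRE at 20.2%. ETS1 overlap with FAIRE dropped to 11.3%, TFIIH overlap with Taf1 dropped to 22.1%, and CBP overlap with ETS1 rose to 20.3%, when the factor lists were reduced to 1262 peaks each. The FAIRE and Taf1 lists were cut there as well, from 11176 and 13518 peaks, so fewer partner peaks were left to overlap. These drops therefore do not show that the strongest ETS1 or TFIIH peaks overlap less. TFIIF peaks of highest area were on chromosome 18 at 34918661 to 34919140, chromosome 5 at 140894741 to 140895200 and chromosome 13 at 105607021 to 105607380, each with FAIRE, TFIIB, TFIIE and total Pol II peaks. The leading CBP peaks, on chromosome 8 at 125225741 to 125226160, chromosome 9 at 20456001 to 20456280 and chromosome 16 at 32660271 to 32660610, overlapped FAIRE but neither TBP nor total Pol II. The remaining ETS1 peaks of the named set, on chromosome 9 at 42273721 to 42274140 and chromosome 10 at 4961891 to 4962450, overlapped TFIIE and TFIIF.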

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

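The contrast between H3K4me3-marked and H3K4me1-only sites was set side by side for CBP and ETS1 anchors, and 2 of 10 factors differed between the anchors by the bootstrap interval of the difference itself. For total Pol II the contrast was 38.8 points at CBP sites and 43.3 points at ETS1 sites, which differed by -4.51 points (-8.12 to -0.613). With peaks within 500 bp counted as overlapping it was -2.56 points (-6.33 to 1.37), and in the upper 50% of each list by area -12.7 points. The latter setting also cut the H3K4me3 and H3K4me1 lists, so sites changed class. For TFIIA it was 6.32 and 3.34 points, a difference of 2.98 points (0.479 to 5.22), which was 2.15 points (-1.01 to 5.39) in the upper 50% of each list. Neither call was adjusted for the 10 comparisons. The number of factors that differed was 5 with an overlap of at least 50% of the shorter interval, 7 with factor lists of equal length, 6 with the H3K4me3 class widened to 1000 bp and 4 with H3K4me3 peaks of the upper 50% by area only. With factor lists of equal length the total Pol II value turned to 4.69 points (1.23 to 9.46). With CBP and ETS1 sites limited to those with a FAIRE peak, an alternative chosen after seeing the data, the values were -3.84 and 2.20 points and neither interval excluded 0, while 3 of the 9 factors other than FAIRE differed there.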

How the results depend on the processing

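The restriction to platforms or sites with a FAIRE peak, the subtraction of chance sites, the matching on area and 2 versions of the width comparison were chosen after seeing the data. Of 271 recomputed occupancy differences at platforms, 174 kept their direction and their side of the threshold and 52 changed sign. Of 190 differences at CBP and ETS1 sites, those between the 2 anchors included, 170 did so and 5 changed sign. The Ser5P minus Ser2P contrasts, the folds over uniform shuffling and the difference in the number of factors between wide and narrow H3K4me3-marked platforms kept their direction and, where tested, their call in every alternative run. Lists reduced to equal length left 10 H3K4me1-only and 5 unmarked platforms, too few to weigh their occupancies. Read numbers were unknown, so it could not be told which peaks were missed for want of depth. The class by distance to start sites was not run. No paired analysis was possible because each target had 1 list. A kept call did not mean a kept size, since 39 of 145 called differences at platforms and 36 of 170 at CBP and ETS1 sites that kept direction and call moved by over 1.5 times. The differences that lost or gained a call or changed sign, and the shares, counts and ratios that moved, follow, with differences in percentage points, and where not stated above the cause was not tested.

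With an overlap of at least 50% of the shorter interval, 63.1% of total Pol II peaks, 75% of Ser5P, 13.1% of Ser2P, 61.3% of TBP, 66.3% of TFIIB, 58.0% of TFIIE, 26.2% of CBP, 55.9% of ETS1 and 39.5% of FAIRE lay in H3K4me3 peaks. 56.7% of TBP overlapped total Pol II, 46.0% of total Pol II overlapped TBP, 49.8% of TFIIB overlapped TBP, 59.0% of TFIIE overlapped total Pol II, 18.2% of CBP overlapped FAIRE and 43.6% of ETS1 overlapped FAIRE. Ser2P gave -1.36 and TFIIE 2.06 for H3K4me3-marked minus H3K4me1-only platforms. H3K4me1-only platforms gave 0.364 factors for the widest minus narrowest quintile. TFIIF gave 1.27 at CBP sites. 5 of 10 factors differed between CBP and ETS1 sites. With peaks within 500 bp counted as overlapping, 67.9% of total Pol II peaks, 86.7% of Ser5P, 17.5% of Ser2P, 74.0% of TBP, 9.77% of Taf1, 20.6% of TFIIA, 75.2% of TFIIB, 64.9% of TFIIE, 40.6% of TFIIF, 24.7% of TFIIH, 34.4% of CBP, 67.6% of ETS1 and 53.0% of FAIRE lay in H3K4me3 peaks. 70.8% of TBP overlapped total Pol II, 62.6% of total Pol II overlapped TBP, 64.4% of TFIIB overlapped TBP, 69.6% of TFIIE overlapped total Pol II, 38.7% of TFIIH overlapped Taf1, 27.3% of TFIIA overlapped Taf1, 32.6% of ETS1 overlapped CBP, 13.1% of CBP overlapped ETS1, 25.8% of CBP overlapped FAIRE and 52.1% of ETS1 overlapped FAIRE. Taf1 gave -0.672, TFIIA 0.165, TFIIE 5.35 and FAIRE 5.14 for H3K4me3-marked minus H3K4me1-only platforms. TFIIE gave 7.39 for H3K4me3-marked minus unmarked platforms. Total Pol II gave -2.56 for CBP minus ETS1 sites. With the upper 50% of each list by area, 67.5% of total Pol II peaks, 72.8% of Ser5P, 62.7% of TBP, 7.04% of Taf1, 15.4% of TFIIA, 65.1% of TFIIB, 51.6% of TFIIE, 26.8% of TFIIF, 14.8% of TFIIH, 24.1% of CBP, 41.2% of ETS1 and 40.0% of FAIRE lay in H3K4me3 peaks. The H3K4me3 and H3K4me1 lists were cut in this setting too, unlike in that of 1262 peaks. These lower shares therefore do not show that stronger peaks lie less often in H3K4me3 peaks. 64.3% of TBP overlapped total Pol II, 53.8% of total Pol II overlapped TBP, 62.5% of TFIIB overlapped TBP, 58.9% of TFIIE overlapped total Pol II, 43.4% of TFIIH overlapped Taf1, 36.6% of TFIIA overlapped Taf1, 22.6% of CBP overlapped FAIRE and 41.7% of ETS1 overlapped FAIRE. 3520 H3K4me3-marked and 566 unmarked platforms were found. Taf1 gave 3.83, TFIIA 2.75, TFIIB -4.52, TFIIE 3.52, TFIIH 1.02, ETS1 -6.94 and FAIRE -2.71 for H3K4me3-marked minus H3K4me1-only platforms. Ser2P gave 0.253, TFIIE 11.7 and CBP -3.47 for H3K4me3-marked minus unmarked platforms. H3K4me1-only platforms gave 0.985 factors for the widest minus narrowest quintile. ETS1 gave -0.758 at CBP sites. FAIRE gave 1.07 and CBP 1.14 at ETS1 sites. TFIIA gave 2.15 for CBP minus ETS1 sites. With factor lists reduced to 1262 peaks, 91.3% of total Pol II peaks, 93.7% of Ser5P, 17.0% of Ser2P, 91.0% of TBP, 9.90% of Taf1, 24.3% of TFIIA, 93.8% of TFIIB, 92.9% of TFIIE, 24.6% of TFIIH, 54.6% of CBP, 69.6% of ETS1 and 59.3% of FAIRE lay in H3K4me3 peaks. 51.3% of TBP overlapped total Pol II, 50.2% of TFIIB overlapped TBP, 59.4% of TFIIE overlapped total Pol II, 22.1% of TFIIH overlapped Taf1, 20.7% of TFIIA overlapped Taf1, 20.1% of ETS1 overlapped CBP, 20.3% of CBP overlapped ETS1, 13.9% of CBP overlapped FAIRE and 11.3% of ETS1 overlapped FAIRE. 601 H3K4me3-marked, 10 H3K4me1-only and 5 unmarked platforms were found. The ratio of median widths of H3K4me3-marked over H3K4me1-only platforms was 1.02. Ser5P gave 5.19, Ser2P 3.00, Taf1 7.65, TFIIB -20.8, TFIIE 0.865, TFIIF -1.51, TFIIH -20.9, CBP -33.7 and ETS1 12.6 for H3K4me3-marked minus H3K4me1-only platforms. Ser5P gave -14.8, Ser2P 3.00, Taf1 7.65, TFIIA -30.7, TFIIB -20.8, TFIIF 8.49, TFIIH -10.9, CBP -3.69 and FAIRE -22.5 for H3K4me3-marked minus unmarked platforms. H3K4me1-only platforms gave -0.500 factors for the widest minus narrowest quintile. Taf1 gave -0.478 and TFIIF 1.60 at CBP sites. Taf1 gave 0.290, TFIIF 2.43 and FAIRE -0.0115 at ETS1 sites. Total Pol II gave 4.69 for CBP minus ETS1 sites. 7 of 10 factors differed between CBP and ETS1 sites. With autosomes only, 46.9% of FAIRE peaks lay in H3K4me3 peaks. Taf1 gave -3.13 and TFIIE 0.288 for H3K4me3-marked minus H3K4me1-only platforms. With platforms from Ser5P Pol II and TBP, 210 H3K4me1-only and 608 unmarked platforms were found. Ser2P gave -3.19, Taf1 0.830 and TFIIB 1.93 for H3K4me3-marked minus H3K4me1-only platforms. TFIIE gave 20.0 for H3K4me3-marked minus unmarked platforms. H3K4me1-only platforms gave 0.810 factors for the widest minus narrowest quintile. With total Pol II peaks alone as platforms, 11606 H3K4me3-marked, 1605 H3K4me1-only and 4826 unmarked platforms were found. Ser2P gave -16.2, Taf1 0.504, TFIIA 1.66, TFIIE 18.1, TFIIH 0.441, CBP -2.03, ETS1 1.77 and FAIRE 12.3 for H3K4me3-marked minus H3K4me1-only platforms. TFIIE gave 13.1 for H3K4me3-marked minus unmarked platforms. H3K4me1-only platforms gave 0.667 factors for the widest minus narrowest quintile. With peaks up to 500 bp apart joined, Taf1 gave -1.10, TFIIE 4.98 and FAIRE 7.01 for H3K4me3-marked minus H3K4me1-only platforms. TFIIE gave 4.17 for H3K4me3-marked minus unmarked platforms. With the H3K4me3 class widened to 1000 bp, Taf1 gave -3.20 and ETS1 -4.17 for H3K4me3-marked minus H3K4me1-only platforms. TFIIE gave -3.51 for H3K4me3-marked minus unmarked platforms. 6 of 10 factors differed between CBP and ETS1 sites. With H3K4me3 peaks of the upper 50% by area only, 1307 H3K4me1-only platforms were found. Taf1 gave 3.07, TFIIA 2.35, TFIIB 1.90, TFIIE 3.93, TFIIH 0.273, ETS1 -8.50 and FAIRE -1.81 for H3K4me3-marked minus H3K4me1-only platforms. TFIIE gave 5.63 for H3K4me3-marked minus unmarked platforms. H3K4me1-only platforms gave 0.830 factors for the widest minus narrowest quintile. TFIIF gave 1.97 and ETS1 -0.397 at CBP sites. CBP gave 2.74 at ETS1 sites. 4 of 10 factors differed between CBP and ETS1 sites. With classes matched on width, Ser2P gave -1.61, TFIIA -7.10, TFIIB -3.06, TFIIE -15.4, ETS1 -5.46 and FAIRE -5.18 for H3K4me3-marked minus H3K4me1-only platforms. With platforms with a FAIRE peak only, Ser2P gave 0.95, Taf1 10.4, TFIIA 8.06, TFIIB 5.33, TFIIE 2.37, TFIIF -0.0272, TFIIH 6.10 and ETS1 -7.58 for H3K4me3-marked minus H3K4me1-only platforms. Ser5P gave -5.59, Ser2P -2.71, Taf1 3.99, TFIIA -2.56, TFIIE 14.5, TFIIF 2.84, TFIIH 13.6 and CBP 6.29 for H3K4me3-marked minus unmarked platforms. With chance unmarked-type sites subtracted, Taf1 gave 1.48, TFIIA 0.170, ETS1 -4.42 and FAIRE -0.416 for H3K4me3-marked minus H3K4me1-only platforms. With classes matched on Pol II and TBP area, Ser2P gave -1.66, TFIIA -7.60, TFIIB -2.86, TFIIE -15.8, ETS1 -4.33 and FAIRE -4.03 for H3K4me3-marked minus H3K4me1-only platforms. With CBP and ETS1 sites with a FAIRE peak only, TFIIF gave 2.77 and ETS1 3.91 at CBP sites. CBP gave 6.98 at ETS1 sites. Total Pol II gave -3.84 and TFIIA 2.20 for CBP minus ETS1 sites.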

Other observations

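The FAIRE, TFIIB and other tests at unmarked platforms, the area matching, the subtraction of chance sites and the restriction to platforms with a FAIRE peak were chosen after the results had been seen in part.

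Pol II peaks with and without TBP lay in different chromatin. Of the 9018 total Pol II peaks without TBP, 26.0% (25.1 to 26.9) overlapped H3K36me3, against 1.76% (1.51 to 2.06) of the 9019 with TBP. Conversely, 75.9% of those with TBP and 52.8% of those without overlapped H3K4me3. TBP peaks without Pol II overlapped H3K36me3 at 1.31% and H3K4me3 at 49.7%. The X chromosome was poor in platforms, with 135 H3K4me3-marked, 3 H3K4me1-only and 4 unmarked ones. Unmarked platforms stood at 0.247 per 10 Mb of X, against 6.74 ± 0.859 (SD over 19 autosomes), and H3K4me3-marked ones at 8.34 against 27.3 ± 8.54. Across the autosomes the density of unmarked platforms ranged from 5.02 to 8.07 and that of H3K4me3-marked ones from 17.9 to 51.8. Unmarked ETS1 peaks were the exception among the lists, denser on X (1.48 per 10 Mb) than on autosomes (0.432).

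Unmarked platforms combined Pol II, TBP, Taf1 and TFIIH peaks with few FAIRE and TFIIB peaks. Whether this was a background taken up by every antibody cannot be told apart from other explanations. FAIRE was 20.1 points (17.7 to 22.6) and TFIIB 26.1 points lower there than at H3K4me3-marked platforms of the same width, but these low shares define the pattern, and low TFIIB had been read first as a sign of such background and then, after the first result, as evidence against it, so neither decides. Ordinary platforms whose histone marks missed the authors' threshold are argued against as the whole cause. The most weakly H3K4me3-marked 20% of marked platforms were matched on width and on both areas to 86.7% of the unmarked ones. They differed from the unmarked ones by -52.5 points (-59.99 to -44.8) in Taf1, -54.7 (-60.8 to -48.4) in TFIIH and -35.2 (-40.3 to -29.8) in TFIIA. These values lay beyond a bound set before they were computed but after earlier readings of this explanation. High shares of these factors at unmarked platforms were already part of the pattern. Their low shares over all H3K4me3-marked platforms, 11.1%, 18.9% and 12.5%, were known as well, so the bound was likely to be met. The argument rests only on the shares staying low, at 11.2%, 10.5% and 6.98%, where the H3K4me3 mark was weakest. CBP (-3.12 points, -11.6 to 5.52) did not differ by its interval. Against all marked platforms matched in the same way, TFIIB was 21.9 points lower at unmarked ones, an earlier reading that decides nothing here. A background limited to the libraries of some targets remains open and was not tested, ETS1, at 0.186%, had been precipitated on other beads and decides nothing here, and no biological explanation was tested.

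Ser5P was less frequent at H3K4me1-only than at H3K4me3-marked platforms. Matching on Pol II and TBP area lowered the difference from 33.9 to 17.0 points (12.7 to 20.9), so weaker signal may account for part of it. The areas were matched only by quintiles, within which marked platforms could still be stronger, and this balance was not checked. Whether weaker signal accounts for all of the difference was therefore left open. Subtracting the unmarked-type sites expected by chance left 32.9 points (28.4 to 37.1). That step could not decide, since it removed only 39.1 of the 469 H3K4me1-only platforms, too few to close the difference. FAIRE peaks lay at only 4.40% of unmarked platforms. At platforms with a FAIRE peak the Ser5P difference was 33.2 points (27.1 to 39.5), which argues against unmarked-type sites as its whole source. It does not exclude other background, since the FAIRE track name recorded no background subtraction. A lower phosphorylation of Pol II at H3K4me1-only sites is a hypothesis that these lists leave open, as is a Ser5P peak threshold that differs from that of total Pol II, and neither was tested.

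CBP, TFIIF and TFIIH peaks were more frequent at H3K4me1-only than at H3K4me3-marked platforms. For CBP the difference was -13.8 points (-19.2 to -9.34) after the sites expected by chance, 39.1 of the 469 platforms (8.34%), were subtracted. CBP peaks lay at 22.2% of unmarked and 27.5% of H3K4me1-only platforms, so this subtraction could only enlarge the difference and decides nothing. At platforms with a FAIRE peak, 176 of them H3K4me1-only, the CBP difference was -12.6 points (-20.8 to -3.92). This argues against unmarked-type sites, few of which had a FAIRE peak, as its whole source. The FAIRE track name recorded no artefact removal or background subtraction, so a FAIRE peak does not exclude other background. With total Pol II alone, however, the CBP difference was -2.03 points and no longer passed. For TFIIF and TFIIH it was -4.90 points (-7.94 to -1.93) and -4.70 points (-7.61 to -2.47) after subtraction, and an interval below 0 there had been set in advance as excluding background sites. That bound was inadequate and was set aside after the first result, because the subtraction assumes random placement and at platforms with a FAIRE peak the values were -0.0272 and 6.10 points, so background sites and recruitment cannot be told apart for these 2 factors. An excess of background sites in H3K4me1 chromatin beyond chance is a possible explanation that was not tested, and neither was a biological one.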
